A study of Drosophila melanogaster with 10 samples.

How the data were processed

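RNA from fly heads was measured on 10 Affymetrix Drosophila 2.0 arrays, which hold short probes grouped into probe sets. Per the labels, the flies were of the yw strain, total RNA was extracted with Trizol and labelled with biotin, and the arrays cover 6 times of day (ZT, zeitgeber time). ZT3 and ZT15 have 3 arrays each, and ZT7, ZT11, ZT19 and ZT23 have 1 array each. The light schedule, the sex of the flies and whether replicates came from separate cultures are not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

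The authors deposited 1 intensity value per probe set and array, and the submitters' processing notes name GCRMA, a method that corrects background by probe sequence, normalizes the arrays and summarises probes; its version and settings are not given in the sources used here. The deposited intensities run from 5.283 to 8528000. The largest exceeds the 65536 levels of a 16-bit scanner, and its log2 is 23.02 while its natural log is 15.96. GCRMA returns log2 values, so the deposited intensities are likely those log2 values raised to the base e. The natural log of each deposited value was therefore used and read as a GCRMA log2 value. This reading was chosen after the values were seen and departs from the rule fixed beforehand, log2(value + 1), which was run as an alternative. On that other reading differences are larger by 1.44 times.

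Probe sets were named through the platform annotation and a table of reference genes. Of 18769 probe sets other than the 183 controls, 13647 had 1 gene symbol, 402 had several and 4720 had none here. Control probe sets were left out, and 12991 probe sets with a mean of at least 4 over all arrays (a deposited value of 54.6) were tested. The number of arrays limits the precision, as does the difference between array sets described below: the median residual SD over the 6 arrays of ZT3 and ZT15 was 0.372 without and 0.176 with the set as a block.

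ZT15 was compared with ZT3 over their 6 arrays, and a 24-hour cosine was fitted to all 10 arrays with an F test on its 2 terms. Both used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Amplitude is the distance from the fitted mean to the peak. Gene lists fixed before the data were examined were tested with camera at its preset correlation of 0.01 and, for rhythmic genes, with a one-sided Fisher's exact test. Each gene was represented by its probe set with the highest mean, over 10165 genes, and lists needed 5 measured genes.

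Clustering of the arrays separated a set of 4 (ZT3 replicates 1 and 2, ZT15 replicates 2 and 3) from a set of 6 (all others). Both sets hold ZT3 and ZT15, so the set was added as a block in a second fit of each comparison. This block was chosen after seeing the data, and its values stand beside those of the fits fixed beforehand.

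The named genes follow a rule fixed beforehand. For ZT15 against ZT3 it takes the 10 largest changes per direction past the threshold with no overlap between the times. For the rhythm it takes the 15 largest amplitudes. The core clock list and up to 4 genes past the threshold per list were added to both. Genes found with the array set block were named by the same rule, except that no overlap was required only within each array set. Every gene so named for ZT15 against ZT3 also had no overlap over all arrays of both times.

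The fits were tested on simulated data with the real means, spreads and array sets. The simulated sets differed by a constant per probe set, with independent normal noise, which is what the fit with the block assumes. The higher recovery of that fit was thus built in. The simulated false calls need not carry over to the real arrays, where genes vary together. In the simulated comparison of ZT15 with ZT3 over 12991 probe sets, the fit without the block recovered 38% of 50 probe sets changed by 2 log2 units and 0% of those changed by 1; with the block it recovered 80% and 44%. For the simulated rhythm over 12991 probe sets, amplitudes of 1 were recovered in 40% of 50 probe sets without the block and in 84% with it. Among the unchanged probe sets, the simulated comparison of ZT15 with ZT3 gave 0 false calls without the block, beside 86 recovered of 200 changed by 1 to 4 units, and 8 with it, beside 157. The simulated rhythm gave 3 false calls beside 88 recovered of 200 without the block and 9 beside 155 with it. Alternatives covered the filter, the normalization, the variance prior, a pseudocount of 16, left-out arrays, blocks, weights and the list tests.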

Results

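Expression was measured in heads of yw flies at 6 times of day, 4 hours apart from ZT3 to ZT23, on 10 arrays. ZT3 and ZT15 were measured 3 times each and the other 4 times once, so values at ZT7, ZT11, ZT19 and ZT23 have no replicate error. Levels are natural logs of the deposited values, likely equal to GCRMA log2 values; if the deposited values were plain intensities, each difference would be 1.44 times larger on the log2 scale. Fold changes below rest on the first reading.

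The arrays fell into a set of 4 and a set of 6 that crossed the times of day. Correlations over the tested probe sets were 0.968 to 0.992 within a set and 0.72 to 0.83 between sets, and the first principal component, which separated the sets, held 89.7% of the variance. Over the 6 arrays of ZT3 and ZT15, 7122 probe sets differed between the sets at an adjusted p of 0.05 (limma). Of these, 4265 were higher and 2857 lower in the set of 4. The sets were drawn by clustering from these same values, so the count describes their distance and is no independent test. Over all 10 arrays, 681 probe sets were lower and 44 higher in the set of 4 by over 4. Transcripts of male reproductive organs differed most among the fixed lists. The 14 testis genes had a median of 12.1 in the set of 6 and 4.56 in the set of 4, and all 14 were lower in the set of 4 by over 2. The 13 accessory gland genes, which encode seminal fluid proteins, had medians of 12.6 and 3.68, with 12 lower in the set of 4 by over 2. Mst84Dc, a sperm tail gene, was at 12.7 ± 0.422 (SD, n = 6) and 5.42 ± 1.44 (SD, n = 4). The exception was Acp95EF, which was at 7.24 in the set of 6 and 8.45 in the set of 4. Phototransduction genes were at 11.7 and 12 and neuron markers at 10.6 and 10.4 in the set of 6 and the set of 4. Gene by gene, the median difference, set of 4 minus set of 6, was -0.567 for neuron markers (12 of 15 lower in the set of 4), 0.794 for hemocyte markers and 0.466 for fat body markers. The control probe set for 18S rRNA was higher by 2.78 in the set of 4, and the gap between the 3' and 5' Act5C controls by 0.683.

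**Figure D1:**
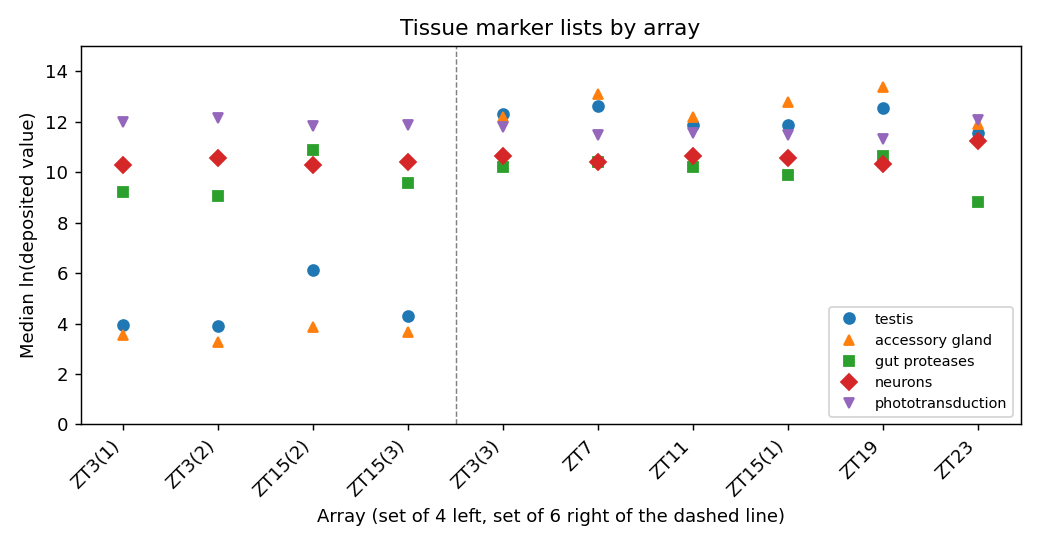
Median level (natural log of the deposited value) of 5 marker lists on each array, 1 symbol per list, with the set of 4 left and the set of 6 right of the dashed line. Testis and accessory gland medians lie between 11.55 and 13.36 on the set of 6 and between 3.26 and 6.12 on the set of 4.

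The comparison of ZT15 with ZT3 asks which transcripts differ between early night and early day, if lights went on at ZT0 as the term's convention has it. Core clock transcripts were the only ones past the threshold without the array set block. tim and per, whose proteins repress their own transcription, and vri, which encodes a repressor of Clk, were higher at ZT15. tim rose from 9.95 ± 0.012 (SD, n = 3) to 13.40 ± 0.097, a difference of 3.45 ± 0.134 (SE) or 10.96-fold. per rose by 3.05 ± 0.133, or 8.28-fold, and vri by 3.05 ± 0.137, or 8.27-fold. The adjusted p was 0.0065 for each (limma) and 0.0025 with the array set as a block. Within the set of 4 and the set of 6 the differences were 3.41 and 3.54 for tim, 2.99 and 3.16 for per, and 3.03 and 3.08 for vri. The other core clock genes passed only with the block or not at all. Clk, which encodes the activator of per and tim, was at 9.28 at ZT3 and 6.92 at ZT15, a difference of -2.37 ± 0.229 (adjusted p 0.17, and 0.046 with the block). cry, the blue-light photoreceptor, differed by -1.49 ± 0.211 (adjusted p 0.63, and 0.031 with the block). Pdp1 differed by 1.04, cwo by 0.90 and cyc by 0.11, with adjusted p of 0.18, 0.13 and 0.85 under the block. Adjusted over the list alone, 7 of 8 core clock genes passed in both fits.

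In all, 4 probe sets passed without the block, all higher at ZT15 (both probe sets of tim, per and vri), and 235 had an unadjusted p under 0.05. These 235 are a smaller share of the 12991 tested than the 0.05 that chance alone would give, so they are no sign of further differences. With the block 1247 had an unadjusted p under 0.05 (limma). With the block 20 passed, 13 higher and 7 lower at ZT15. The genes higher at ZT15 with the block included cyr, Usp8 by 1.87, gol by 1.81, Slob, which encodes a binding partner of the Slowpoke potassium channel, by 1.72, CG14275 by 1.47, the cytochrome P450 gene Cyp4d21 by 1.45 and CG2681 by 1.44. Those lower included CG42329 by a difference of -2.46 ± 0.151 (SE), the cuticle protein gene Cpr72Ec by -2.10, the glycosyltransferase gene Ugt35B1 by -1.83 and CG34134 by -1.70. Their adjusted p under the block lay between 0.023 and 0.050 and without it none passed. cyr was at 3.47 to 4.82 at ZT3, about as low as the testis and accessory gland genes on the set of 4 (medians 4.56 and 3.68), and may not be above background there. Its difference, 3.23 as fitted and 2.42 with a pseudocount of 16, is therefore uncertain in size, and the filter at 6 left it out. The probe sets of gol and Slob disagreed, the others differing by 0.25 and 0.24. The second probe set of CG42329 differed by -2.15 and did not pass (adjusted p 0.14 with the block). Leaving out any 1 of the 6 arrays left 0 probe sets without the block. With the block it left 3 without ZT3 replicate 1, 5 without ZT3 replicate 2, 3 without ZT15 replicate 2, and 0 without ZT3 replicate 3, ZT15 replicate 1 or ZT15 replicate 3.

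**Figure D2:**
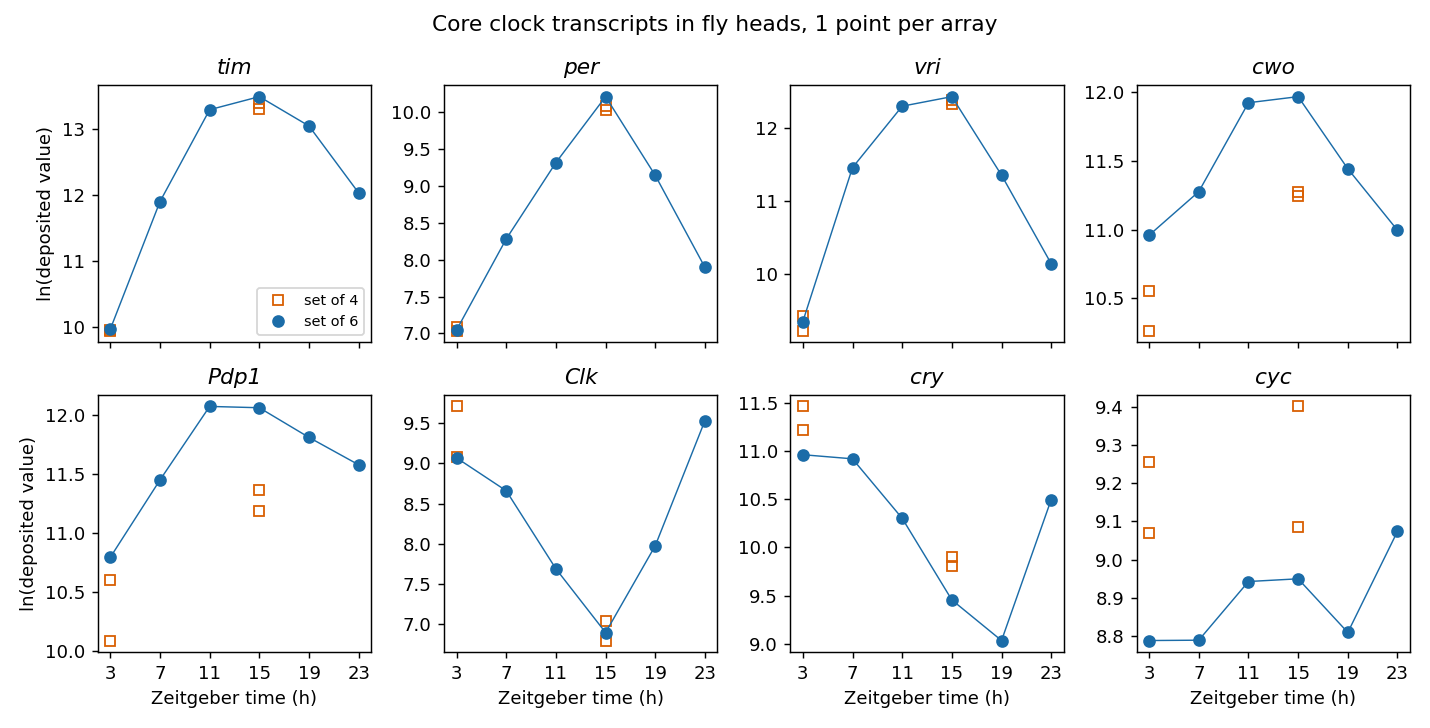
Level (natural log of the deposited value) of 8 core clock transcripts against zeitgeber time in hours, 1 point per array, open squares for the set of 4 and filled circles joined by a line for the set of 6; vertical scales differ between panels. tim, per and vri are lowest at ZT3 on the set of 6, where tim is at 9.96, and highest at ZT15, where it is at 13.50.

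Among the fixed lists, 4 of 28 passed camera for ZT15 against ZT3. The core clock was higher (median 0.97, adjusted p 5.8e-08). Muscle genes were lower (median -0.19, 22 genes), as were glutathione S-transferases (median -0.11, 34 genes) and UDP-glycosyltransferases (median -0.25, 26 genes), each with adjusted p 0.018. With an estimated correlation none passed: adjusted p = 0.21 for the core clock, 0.35 for muscle and 0.52 for both enzyme families. The largest muscle differences were those of the flight muscle genes Act88F (-2.10 ± 1.23, SE with the block), fln (-2.10 ± 1.03) and TpnC4 (-1.11), which were high on ZT3 replicate 3 (Act88F at 11.98, against 8.17 and 8.34 on the other ZT3 arrays). The muscle list did not pass without that array (adjusted p 0.48), without ZT15 replicate 1 (0.072) or 2 (0.12), or without these 3 genes (0.10, an alternative added after seeing the data). Glutathione S-transferases did not pass without ZT3 replicate 2 (0.066), ZT3 replicate 3 (0.10) or ZT15 replicate 1 (0.21), nor UDP-glycosyltransferases without ZT3 replicate 2 (0.066) or ZT15 replicate 1 (0.11), or with no filter on low values (0.057). No single muscle, transferase or glycosyltransferase gene passed on its own without the block, and with it only Ugt35B1 did. With the array set as a block 7 lists passed, namely the core clock (adjusted p 0.0011), odorant-binding proteins (0.016), muscle (0.029), accessory gland (0.029), fat body (0.031), UDP-glycosyltransferases (0.034) and testis (0.038), while glutathione S-transferases were at 0.055; 0 passed with an estimated correlation, with adjusted p of 0.67, 0.71, 0.71, 0.71, 0.79, 0.67 and 0.85 in the same order. Testis and accessory gland genes are the lists that separated the array sets. On the set of 4 the testis median was 3.93 and 3.89 at ZT3. It was 6.12 on ZT15 replicate 2 and 4.3 on ZT15 replicate 3, so its rise was largest on a single array. On the set of 6 it was lower at ZT15 (11.87) than at ZT3 (12.29). The accessory gland median was 3.56 and 3.26 at ZT3 and 3.87 and 3.66 at ZT15 on the set of 4, and 12.17 and 12.77 on the set of 6. Without the block, 8 lists passed when ZT3 replicate 3 or ZT15 replicate 3 was left out. Several large lists had no member past the threshold and did not pass: 41 cytoplasmic ribosomal proteins (adjusted p 0.65), 74 oxidative phosphorylation genes (0.18), 39 proteasome genes (0.36), 18 phototransduction genes (0.36), 11 antimicrobial and immune-induced peptides (0.28) and 9 heat shock genes (0.16). Adjusted over the list alone, as given for the core clock, 1 phototransduction gene passed without the block and 2 with it. No gene of the other lists in the sentence before did in either fit. By that measure 4 of 34 glutathione S-transferases and 3 of 26 UDP-glycosyltransferases passed with the block.

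The cosine fit asks which transcripts followed a 24-hour cycle over the 6 times. CG34134 had the largest amplitude, 3.07 ± 0.132 (SE), with a fitted peak at ZT22.1; it was at 13.41 at ZT23 and 7.18 at ZT11. The clock genes vri (amplitude 1.59 ± 0.137, peak ZT13.4), per (1.48 ± 0.073, peak ZT14.6) and Clk (1.24 ± 0.126, peak ZT1.96) and the P450 gene Cyp4d21 (0.83 ± 0.087, peak ZT17.2) also passed. Adjusted p (limma) was 0.00022 for CG34134, 0.019 for vri, 0.00043 for per and 0.050 for Clk and Cyp4d21. The calls of Clk and Cyp4d21 ended after quantile normalization (adjusted p 0.051 each), as they did without any 1 array. They stayed on the log2(value + 1) scale with the same 12991 probe sets (0.050 each) and ended when the filter was also set on that scale, with 16033 probe sets (0.055 each). The call of Cyp4d21 also ended after median centring (0.056). These 5 were the probe sets past the threshold without the block, and 209 had an unadjusted p under 0.05. That is again a smaller share of the 12991 tested than the 0.05 that chance alone would give. With the block 1028 had an unadjusted p under 0.05 (limma).

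With the array set as a block 66 probe sets passed, the same 5 among them, with amplitudes from 0.346 to 3.07 and a median of 0.818. Of the 66, 15 peaked from ZT0 to ZT3 and 11 from ZT3 to ZT6, none from ZT6 to ZT12, 25 from ZT12 to ZT18, 5 from ZT18 to ZT21 and 10 from ZT21 to ZT24. Most arrays were at ZT3 or ZT15, so rhythms with peaks near these times were easier to detect. The counts may partly reflect this design, but it does not account for the gap from ZT6 to ZT12. The F test ignores the sign of a rhythm, so peaks from ZT6 to ZT12 were as detectable as those from ZT18 to ZT24. The cause of the gap was not tested. Of the 20 probe sets that differed between ZT15 and ZT3 under the block, 19 were among the 66. Both fits used the same ZT3 and ZT15 arrays, so this overlap is no independent evidence. tim (amplitude 1.65 ± 0.150, peak ZT14.9), cry (0.93 ± 0.093, peak ZT5.12) and cwo (0.52 ± 0.057, peak ZT13.3) passed with the block, at adjusted p of 0.0096, 0.011 and 0.021, as did Usp8 (1.28, peak ZT12.2) and Slob (0.87, peak ZT15.9). The second probe sets of cwo (adjusted p 0.085) and Slob (0.74) did not pass. Pdp1 had an amplitude of 0.51 (adjusted p 0.12) and cyc one of 0.058 (adjusted p 1.0). Peaks late at night were fitted for Achl (amplitude 3.07, ZT21.3), CG14636 (1.23, ZT21.6) and CG8419 (1.47, ZT19.7). Near dawn peaked CG13305 (1.54, ZT0.939), CG42329 (1.49, ZT1.10), Cpr72Ec (1.08, ZT2.12) and Ugt35B1 (1.03, ZT1.43). cyr (1.47) and CG14221 (1.18) peaked at ZT15.9 and ZT17.9. Lsp2, a larval serum protein gene of the fat body, had an amplitude of 1.20 and a peak at ZT19.6, and Jhbp15 had 1.10 and ZT1.92; both differed widely between array sets, with SDs of 1.81 and 2.48 over the 3 ZT3 arrays. The lowest values of CG14221 (3.76 at ZT7), Achl (3.69 at ZT7) and Jhbp15 (3.40 at ZT11 and on ZT15 replicate 1), like those of cyr, may not be above background, so these amplitudes are uncertain in size: with a pseudocount of 16 they were 1.09 for cyr, 0.78 for CG14221, 2.51 for Achl and 0.87 for Jhbp15, which no longer passed (adjusted p 0.16 with the block). Among glutathione S-transferase, UDP-glycosyltransferase and P450 genes, GstZ2 (0.81, ZT2.25), GstD10 (0.40, ZT3.31), Ugt302C1 (0.42, ZT2.24) and Cyp305a1 (0.39, ZT3.96) had fitted peaks in the early day. Cyp18a1, whose product inactivates the moulting hormone 20-hydroxyecdysone, had a fitted peak at ZT17.0 (0.71), and its second probe set did not pass (adjusted p 0.17). With the block, 72 probe sets passed without ZT19, 41 without ZT23, 23 without ZT7 and 18 without ZT11; 18, 16 and 22 passed without ZT3 replicates 1, 2 and 3, and 18, 13 and 16 without ZT15 replicates 1, 2 and 3. Without the block, 4 passed without ZT23, 3 without ZT7 and 2 without any other single array.

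**Figure D3:**
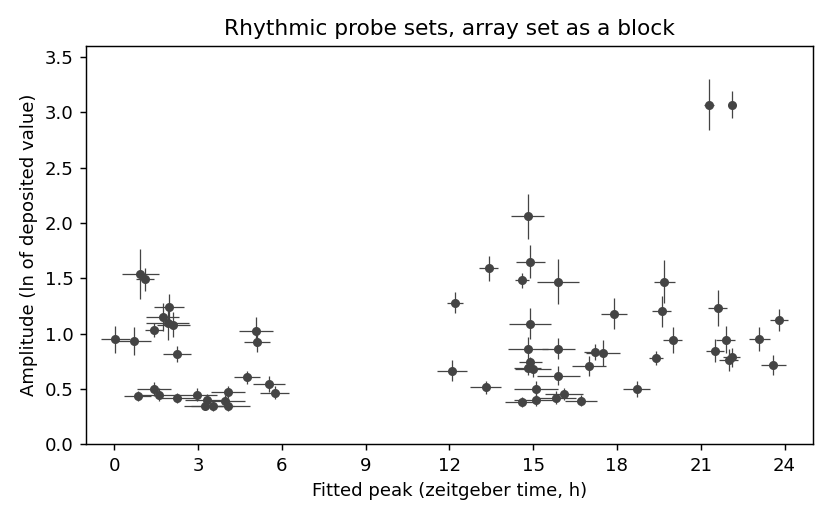
Fitted amplitude (natural log of the deposited value) against fitted peak (zeitgeber time in hours) for the 66 probe sets past the threshold with the array set as a block, 1 point per probe set with bars of 1 SE. No peak lies between ZT6 and ZT12, and the largest amplitudes are 3.07. Most arrays were at ZT3 or ZT15, so peaks near these times were easier to detect. This does not account for the gap, since peaks from ZT18 to ZT24 were no easier to detect than those from ZT6 to ZT12.

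Of 5 rhythmic genes in the fixed fit, 3 were core clock genes (Fisher's exact test, adjusted p 9.0e-08). With the block 6 of 8 core clock genes were among 58 rhythmic genes (adjusted p 2.1e-11), and so were 5 of 12 genes on a list of head cyclers recalled from earlier fly array studies (5.5e-08). That list may draw on these same samples, so it is not independent evidence. Adjusted over the list alone, 6 and 7 of 8 core clock genes were rhythmic without and with the block. No other list passed; 3 of 74 cytochrome P450 genes (adjusted p 0.067), 2 of 34 glutathione S-transferases (0.089) and 2 of 26 UDP-glycosyltransferases (0.067) were rhythmic with the block.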

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

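The array set block, the single-set fits and all alternatives to the block fits were chosen after seeing the data, as was the natural log in place of the log2(value + 1) scale fixed beforehand, which is given here as an alternative. For ZT15 against ZT3 the count of 4 probe sets was 4 or 5 under the filters, normalizations, pseudocount, variance prior, log2(value + 1) scale with either filter and fit over all 10 arrays, 20 with the array set block, 0 in the set of 4 only and 0 to 0 without 1 replicate, where fewer arrays leave fewer degrees of freedom. The replicate numbers do not pair the samples: same-numbered deviations correlated at -0.893, 0.804 and -0.903, and with the replicate number as a block 0 probe sets passed (limma, 235 at an unadjusted p under 0.05 without it). The difference of cyc, 0.11, ranged from -0.020 to 0.216 without 1 replicate and was below 0 without ZT3 replicate 3 (-0.017) or ZT15 replicate 3 (-0.020); the cause was not tested. With the array set block the 20 became 13 after quantile normalization, 102 with trend and robust variance and 0 to 5 without 1 replicate.

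For the 24-hour rhythm the count of 5 was 3 after quantile normalization, 5 on the log2(value + 1) scale with the same probe sets, 3 with the filter also set on that scale, 9 with trend and robust variance, 2 to 4 without 1 array, 0 with 1 value per time, 66 with the array set block and 0 in the set of 6 only. The last and the 1-value fit rest on 6 values. The 66 of the block became 13 to 72 without 1 array and 6 in an F test over 6 time means. For gene lists at ZT15 against ZT3 the 4 lists were 0 with an estimated correlation, 1 with fry, 7 with the array set block, 0 with the block and an estimated correlation, and 4 to 8 without 1 replicate. For rhythmic gene lists the 1 list became 2 at an adjusted p of 0.1, 0 with 1 value per time and 2 with the array set block. The causes were not tested. For named genes, 24 of the alternative values of ZT15 minus ZT3 lost and 14 gained significance, while 301 kept their outcome. The 24 were those of tim, per and vri, each in 8 of 18 alternatives. Under the block 97 lost it, 2 gained it and 185 kept their outcome. Of the amplitudes, 43 lost it, 23 gained it and 519 kept their outcome. Under the block 146 lost it, 0 gained it and 355 kept their outcome. Most of these genes were named because they passed under the block, so more losses than gains there follow from the choice.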

Other observations

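The tests on labelling and on the time of day, and the correlations of fln, TpnC4 and the rest of the muscle list, were chosen only after the result was seen.

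Several tissue markers stood apart on single arrays. Of 12 eggshell and oocyte genes, 8 were highest at ZT11, 6 of them by over 2, while Cp18 and bcd were not. Cp36 was at 10.6, Vm26Aa at 11.44 and osk at 8.83 there, against 3.64 to 3.99, 4 to 4.91 and 3.08 to 6.74 on the other arrays of the set of 6. Cp15 was at 12.29 on ZT3 replicate 3 and 7.34 at ZT11. Gut protease genes were present on both sets, with alphaTry at 13.86 on the set of 4 and 14.07 on the set of 6. The yolk protein gene Yp1 was at 15.87 and 15.68.

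Testis and accessory gland transcripts on the set of 6 may come from male reproductive tissue in those samples. Seminal fluid, S-Lap and other Mst genes outside both lists had a median difference, set of 4 minus set of 6, of -5.2, with 16 of 19 lower by over 2. After quantile normalization of all 10 arrays the median over both lists was -7.48, so a difference in the arrays' value distributions does not account for the gap. The medians of all probe sets differed by only -0.628 between the sets, so this step could hardly have closed it. It also cannot undo background correction or summarising done in separate groups, so processing in separate groups stays open. Of 27 listed genes, 26 differed by more than 3 times 0.683, the largest set difference in the gap of 3' and 5' controls. That largely restates the differences by over 2 already given. Other controls differed more between the sets, 18S rRNA by 2.775 and bioB by 1.727. Still, 25 of the 27 genes were lower in the set of 4 by over 4, more than any of these controls. This comparison was chosen after the result was seen, so labelling or RNA integrity is not excluded. How male reproductive tissue would enter head samples stays open and was not tested, since the labels give no sex or dissection.

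The flight muscle genes Act88F, fln and TpnC4 were high on ZT3 replicate 3, ZT11 and ZT19, where Act88F was at 11.98, 12.1 and 13.4, against 5.96 to 8.5 on the other arrays of the set of 6. Flight muscle tissue in some samples was tested first by these genes themselves: the lower Pearson r with Act88F was 0.955 for TpnC4 (exact permutation p 0.0028, Benjamini-Hochberg 0.0046 over 5 genes; Spearman rho 1, exact p 0.0028; r 0.908 without the 2 farthest arrays), which decides nothing because they showed the pattern. A second test named 10 further muscle genes, of which 3 lay outside the muscle list (sals, Gpdh1, Msp300); their median r was -0.195, but they are not specific to flight muscle, and in the list itself Act79B had r 0.956 and the 19 genes other than these 3 flight muscle genes a median r of 0.654, so tissue that brings other muscle transcripts along stays open. Within the set of 6, time of day cannot be told apart from single arrays, since it has 1 array per time. In the set of 4 Act88F differed by at most 0.326 between arrays of 1 time. It was at 8.17 and 8.34 at ZT3 there and at 7.95 and 8.28 at ZT15, against 11.98 and 5.96 in the set of 6. fln was at 5.4 and 7.1 against 5.62 and 5.66 in the set of 4, and at 10.58 against 5.5 in the set of 6. For these 2 genes the values argue against time of day as the source of the difference between ZT3 and ZT15. For ZT11 and ZT19 it stays open.

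Varying amounts of body tissue stay open as a source of the rhythmic probe sets under the array set block. Over the 6 arrays of the time course, the median absolute r with the testis and accessory gland mean was 0.181 for the 66 called and 0.592 for the other probe sets, a difference of -0.411. That test decides nothing, since only 2.23% of the variance of that mean lay on a 24-hour cosine, which leaves probe sets called by the cosine little room to follow it.

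Other assignments of the arrays were counted. For ZT15 against ZT3, 1 of 10 splits (the real one) gave 4 probe sets and the highest other gave 0; with the block, 1 of 6 splits within the sets gave 20 and the highest other 0; both have too few splits for a share under 0.05. For the rhythm, 3 of 100 assignments of the times over all arrays gave 5 or more, the real one included. The highest others gave 4230 and 4886, many times the real count. In these the set of 4 received only times from ZT3 to ZT11 and from ZT7 to ZT15, so the cosine could take up the difference between the array sets. Assignments over all arrays move times across the array sets, so their count does not settle chance for the fit without the block. Within the sets, for the fit with the block, 1 of 100 (the real one) gave 66 and the highest other gave 25. That share, under 0.05, bears on the count as a whole. It does not exclude chance for any single one of the 66 calls, and the block itself was chosen after seeing the data.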
